A study of Homo sapiens with 14 samples.

How the data were processed

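RNA of 4 parental OVCAR-3 samples and of 5 PHA-533533-resistant sublines, each sampled at passage 5 in 4 µM inhibitor and again at passage 10 or later in 0 µM, was hybridised to Affymetrix whole-transcript arrays with a biotin label, per the labels. The deposited values are used as log2 signal. The labels give no scale, and base 2 was taken from the range of the values, 4.34 to 14.9 over the 14 arrays. Background correction, normalization and summarisation are not given in the sources used here, so a difference between arrays may hold effects of steps that are unknown. The median over all table rows lay between 7.54 and 7.68 per array. No scan date or batch was used here.

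The value table has 32295 rows. The platform annotation names 1 gene for 19148 rows and several for 1376, and 11771 rows are unnamed here. Symbols were updated by gene ID through a RefSeq gene table (GRCh38.p14), which held the gene of 19118 of the 19148 rows. Its chromosomes and start positions were used only to put genes in order, and no coordinate is printed. For the 633 genes with more than 1 row the row with the highest mean was kept, which left 18398 genes. No filter on dim genes was applied in the tests reported first.

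Groups follow the labels. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Selected against parental and stable against parental used 9 arrays each and selected against stable 10, with no covariates. Each subline against parental used all 14 arrays as 6 groups, and the difference between sublines was an F test over the 10 resistant arrays with growth condition as a covariate. Replicate numbers of selected and stable arrays name the same subline, so subline pairs them by the labels. The correlation of paired deviations from the group means across genes was 0.636 in R1, 0.050 in R3, 0.371 in R5, 0.546 in R6 and -0.468 in R7. Among the 5 stable arrays the selected array matched its own subline best in R1 and R6, while R3 matched R5 (0.118), R5 matched R7 (0.637) and R7 matched R1 (0.397). The blocked fit is given where it changes a call or moves a printed count by over 1.5 times.

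Before the data were examined 30 gene lists with 808 symbols were fixed, of which 741 were measured. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, under which no list was called, and with fry, and adjusted over the 30 lists of each comparison. By fry 4 lists passed for selected against parental, the ribosomal proteins (adjusted p = 0.00812), lysosome and xenobiotic genes (both adjusted p = 0.0201) and interferon response (adjusted p = 0.0202), and 2 for selected against stable, the lysosome and oxidative phosphorylation lists (both adjusted p = 0.0334), neither of which passed by fry with the block (both adjusted p = 0.129). By fry no list passed for stable against parental, nor did the CDK2, oxidative phosphorylation and 19q12 lists (each adjusted p = 0.154) or the centrosome and epithelial lists (both adjusted p = 0.203) for selected against parental. The genes named are CCNE1 and CDK2, the 8 largest rises and 8 largest falls among called genes of each comparison, or where fewer passed up to 4 each way by smallest p, up to 4 members of each list by smallest p, 3 rises and 3 falls per subline, the 8 smallest p between sublines with a range of at least 1, and each gene with an outlying array. Symbols of uncharacterised, small RNA, olfactory receptor and keratin-associated genes were skipped. From the names the rule allowed, those printed were picked after their values were seen.

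The mean of 340 olfactory receptor genes per array was adopted as a measure of background after the data were seen. The first principal component held 37.8% of the variance between arrays and followed this measure. Group differences in it were tested with exact permutations of the arrays.

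Alternatives fixed beforehand were a log2 difference of at least 1, trended and robust variance, array weights, quantile normalization, median centring, a filter at the 40th percentile of mean signal, the mean of all rows of a gene, all rows one by one, 1 fit of all 14 arrays with and without subline as a random block, the subline block, growth condition terms and leaving out each array. Added later were the olfactory receptor mean as a covariate and leaving out subline R7. The fits were tested on simulated data over 18398 genes with 50 changed genes at each of 4 sizes. For selected against parental 64% of changes of 0.5 log2 and 90% of changes of 1 were recovered, for stable against parental 46% and 94%, for selected against stable 50% and 94%, and between sublines 0% and 48%. Up to 8 unchanged genes were called in any simulated comparison. Figures were drawn with matplotlib.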

Results

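OVCAR-3 is an established human ovarian carcinoma cell line known for extra copies of the chromosome region that holds CCNE1, the gene of cyclin E1, which binds and activates the cell cycle kinase CDK2. RNA levels were measured on 14 Affymetrix whole-transcript arrays, 4 of parental cells and 10 of 5 separately derived sublines resistant to PHA-533533, an inhibitor of CDK2. The sublines carry the names R1, R3, R5, R6 and R7. Each was arrayed at passage 5 while growing in 4 µM of the inhibitor, called selected here, and again at passage 10 or later after growth in 0 µM, called stable here. Inhibitor and passage changed together between these arrays, so the 2 cannot be separated by any comparison. Nothing in the labels says that the 4 parental replicates were separate cultures, so p-values against them measure the spread between these samples, which may be technical. Deposited values ran from 4.34 to 14.9 on a log scale taken as base 2, and the number of arrays limits the precision of every value. The mean of 340 olfactory receptor genes, which are silent in most tissues and so track background signal, was 6.42 ± 0.225 (SD, n = 4) in parental, 6.35 ± 0.211 (SD, n = 5) in selected and 6.50 ± 0.212 (SD, n = 5) in stable arrays. It did not separate the groups by more than their spread, with two-sided exact permutation p = 0.595 for selected against parental, p = 0.651 for stable against parental and p = 0.254 for selected against stable. Within the 5 sublines, however, it was lower in the selected array of all 5 pairs (exact sign-flip p = 0.0625, the smallest that 5 pairs allow).

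The comparison of selected with parental cells asks how resistant cells growing in the inhibitor differ from the cells they came from. By the labels the parental cells grew without the inhibitor. Selected against parental therefore cannot separate a response to the inhibitor from acquired resistance. Of 18398 genes, 926 were higher and 347 lower in selected cells, 1273 in all. CCNE1 was 0.45 higher on the log2 scale (SE 0.12, adjusted p = 0.0497), with means of 11.39 ± 0.24 (SD, n = 5) and 10.94 ± 0.15 (SD, n = 4), and this call stood at the threshold, since 10 of 19 alternative settings put its adjusted p, which ranged from 0.0271 to 0.127, above it. CDK2 itself differed by 0.33 (SE 0.11) and did not pass (adjusted p = 0.0964). The largest rises were those of NID2, a basement membrane protein, by 1.64 (SE 0.19), CD44, a receptor for hyaluronan, by 1.46 (SE 0.20), IFNE, an epithelial interferon, by 1.41 (SE 0.29), and RRAGD, a GTPase of nutrient sensing at the lysosome, by 1.39 (SE 0.31), followed by LRCH2 at 1.37, SDCBP at 1.32, MGAT4A at 1.30 and the basal keratin KRT5 at 1.26. The largest falls were those of VIT at -1.76 (SE 0.18), LINC00312 at -1.68 (SE 0.13), MAL at -1.38, TMEM178A at -1.35, LTBP1, which binds latent TGF-beta, at -1.21, SPOCK2 at -1.13, ANKRD34B at -1.12 and RHEX at -1.09. Adjusted p for these 16 genes lay between 0.000377 and 0.0211.

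Among the gene lists fixed beforehand, the lysosome list was called higher in selected cells. Of its 27 measured genes 11 were higher, 0 lower and 16 not called (16 and 0 adjusted over the list alone). Among the 11 were the proteases CTSL at 0.68 and CTSD at 0.53, the membrane protein LAMP2 at 0.51 and the glycoprotein GPNMB at 1.21. The list's adjusted p was 1.87e-09 by camera with a preset correlation and 0.435 with an estimated correlation. Ribosomal protein genes went the other way, with 7 of 36 lower and 0 higher (13 and 0 adjusted over the list alone), among them RPS24 at -0.998, RPL7A at -0.57, RPL13 at -0.55 and RPS9 at -0.43 (adjusted p = 1.76e-09, and adjusted p = 0.329 with an estimated correlation). With the mean of all rows of a gene RPL13 and RPS9 lost their calls, at -0.21 (adjusted p = 0.174) and -0.039 (adjusted p = 0.921). No list was tested with that setting, so how far the list call depends on the row kept is not known. Of 35 oxidative phosphorylation genes 3 were higher, SDHD at 0.43, NDUFS3 at 0.40 and SDHA at 0.33, and 0 lower (5 and 1 adjusted over the list alone, adjusted p = 0.00117, and adjusted p = 0.733 with an estimated correlation). Of 19 genes of CDK2 and cyclin E regulation, 5 were higher and 0 lower (6 and 0 adjusted over the list alone). These were CCNE1, the related cyclins CCNA1 at 0.98 and CCNE2 at 0.74, the cyclin E and CDK2 substrate NPAT at 0.43 and CDKN1A, an inhibitor of CDK2, at 0.59 (list adjusted p = 0.00175, and adjusted p = 0.733 with an estimated correlation).

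Genes of xenobiotic metabolism and NRF2, the regulator of antioxidant genes, had 5 of 26 members higher and 0 lower (10 and 0 adjusted over the list alone), including AKR1C3 at 0.55, AKR1C2 at 0.62, SLC7A11 at 0.68 and ALDH3A2 at 0.37. Interferon response genes had 3 of 26 higher and 0 lower (8 and 0 adjusted over the list alone), namely IFI44L at 1.10, IFI6 at 0.63 and HERC5 at 0.46. Both lists had an adjusted p of 0.00175, and both an adjusted p of 0.435 with an estimated correlation. The p53 target list did not pass (adjusted p = 0.0562, and adjusted p = 0.733 with an estimated correlation), although 5 of its 23 genes were higher and 0 lower (10 and 1 adjusted over the list alone), among them ZMAT3 at 0.62, DDB2 at 0.60 and SESN1 at 0.49. The centrosome list (adjusted p = 0.00319) and the epithelial markers (adjusted p = 0.0149), of which ELF3 rose by 0.63, were called higher, each with an adjusted p of 0.733 with an estimated correlation. The list of genes in and beyond the 19q12 region around CCNE1, the 19q12 list here, was called lower (adjusted p = 0.00876, and adjusted p = 0.599 with an estimated correlation). Of its 22 genes CCNE1 rose, ANKRD27 fell at -0.42, and URI1, at -0.25, did not pass (adjusted p = 0.148).

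DNA replication genes moved both ways, with 2 of 39 higher, DTL at 0.57 and E2F1 at 0.31, and 3 lower, GINS4 at -0.78 and MCM7 at -0.46 among them (list adjusted p = 0.397). The mitotic kinase AURKB fell at -0.50, the only gene of 36 on the mitosis list to be called (list adjusted p = 0.718). CCND3, a D-type cyclin, rose by 0.45 while its partner kinase CDK6 fell at -0.73. The immediate early genes EGR1 and FOSB fell at -0.59 and -0.92, CCN1 and AXL at -0.57 and -0.46, and TNFAIP2, ICAM1 and SAV1 rose by 0.998, 0.74 and 0.49. EGR1 was 12.27 and 12.14 in parental replicates 1 and 3, against 12.82 and 12.81 in replicates 2 and 4. FOSB (9.15 and 9.06 against 10.05 and 10.22) and KRT5 (9.81 and 9.95 against 11.10 and 11.08) parted the same way. So did RHEX (11.08 and 10.77 against 11.60 and 11.66) and ANKRD34B (10.50 and 10.52 against 11.08 and 10.90). FOS (10.45 and 10.44 against 11.26 and 11.31) did as well. TMEM178A (10.99 and 10.68 against 10.26 and 10.23) parted in reverse, while NID2 and VIT did not part. For the genes that parted, the size of a difference from parental cells depends on which parental arrays are used. EGR1, FOSB and KRT5 lost their calls in 9, 7 and 4 of 19 alternatives, and RHEX, ANKRD34B and TMEM178A in 0. Marker lists of fibroblasts, leukocytes, endothelial and mesothelial cells were not called (adjusted p = 0.284, 0.726, 0.380 and 0.747).

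The calls of selected against parental fell to 735 without parental replicate 1, 517 without parental replicate 4, 818 without the selected array of R3 and 621 without that of R7, 44 had a log2 difference of at least 1, and without parental replicate 3 487 were higher and 375 lower. Of the 59 called genes named for this comparison 28 kept their call in all alternatives that set no minimum difference, 14 of them with a log2 difference of at least 1, and ANKRD27 (12 of 19), NPAT (11 of 19) and CCNE1 (10 of 19) lost it in most, while with the olfactory receptor mean as a covariate, a setting added after the data were seen, 2318 genes were called, all of the 1273 among them in the same direction.

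**Figure D1:**
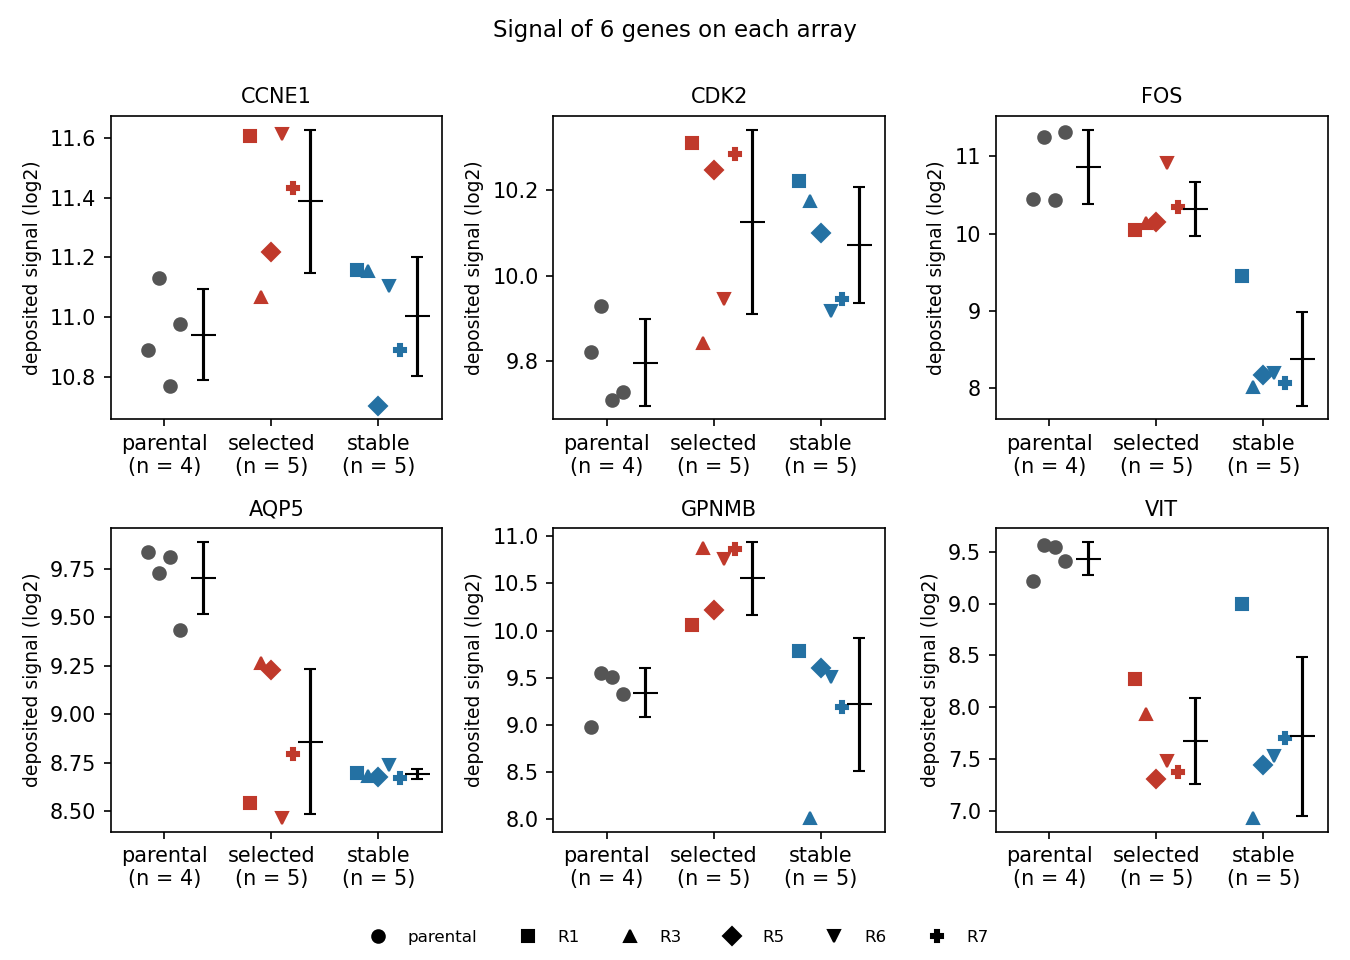
Deposited log2 signal of 6 genes on each of the 14 arrays, by group, with a marker for each subline and the group mean ± SD beside the points (n = 4, 5 and 5). CCNE1 lay higher in selected than in parental cells on average (means 11.39 and 10.94) with overlapping values, while AQP5 lay below all parental arrays in every selected and every stable array.

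Comparing stable with parental cells asks what remained after growth without inhibitor. AQP5, a water channel gene, was the only gene called of 18398. It was lower by limma at -1.01 (SE 0.09, adjusted p = 0.00347), with means of 8.69 ± 0.03 (SD, n = 5) and 9.70 ± 0.19 (SD, n = 4), and an unadjusted p under 0.05 was reached by 1120 genes. Neither CCNE1, at 0.06 (SE 0.11, adjusted p = 0.999), nor CDK2, at 0.27 (SE 0.09, adjusted p = 0.528), passed. None of the next genes by p passed. These were FOS at -2.48 (SE 0.30, adjusted p = 0.0524), TMEM178A at -1.26 and EFEMP1 at -1.36 (adjusted p = 0.0738 for both), and, with positive differences, KLK10 at 0.82, CRYAB at 1.01, ABCA4 at 0.45 and SEL1L3 at 0.72, with adjusted p between 0.0738 and 0.0823. EGR1 and FOSB differed by -1.56 and -1.43 (adjusted p = 0.135 and 0.0881).

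No member of any list was called in stable cells, but 4 lists were called as sets. Adjusted over the list alone no member of these 4 passed either, while 4 genes of the NF-kB list were lower, 1 of the MAPK output list was higher and 3 lower, and 1 each was lower on the CDK4 and CDK6, lysosome, integrated stress response and leukocyte lists. The 19q12 list was lower (adjusted p = 3.32e-06, and adjusted p = 0.580 with an estimated correlation), with 1 of 22 genes above 0 and, as examples that did not pass alone, PLEKHF1 at -0.45, C19orf12 at -0.38 and URI1 at -0.29. Interferon response genes were higher (adjusted p = 3.32e-06, and adjusted p = 0.739 with an estimated correlation), with 22 of 26 above 0 and RIGI at 0.53, IFI27 at 0.50 and TAP1 at 0.32, none of which passed alone. The interferon mean ranged from 0.00 in the stable array of R1 to 0.58 in that of R3. Ribosomal protein genes were lower (adjusted p = 0.000145, and adjusted p = 0.739 with an estimated correlation) and xenobiotic genes higher (adjusted p = 0.0496, and adjusted p = 0.720 with an estimated correlation), a call lost in 11 of 15 alternatives. The lysosome list had a mean difference of 0.01 (adjusted p = 0.755). Without the stable array of R1, 26 genes were called, and with array weights 286.

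**Figure D2:**
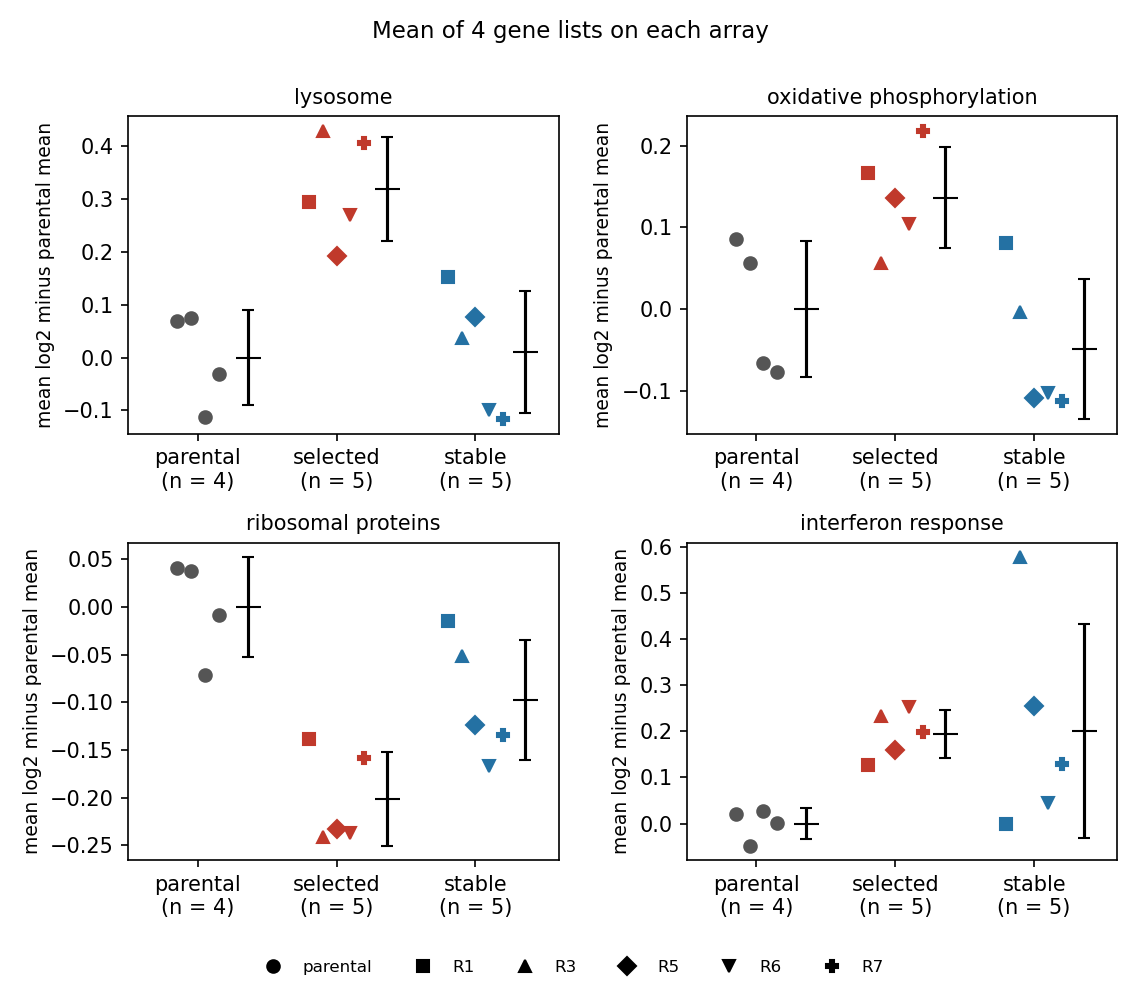
Mean log2 signal of 4 gene lists on each array relative to the parental mean, by group, with a marker for each subline and the group mean ± SD beside the points (n = 4, 5 and 5). The lysosome list averaged 0.32 above parental in selected and 0.01 in stable arrays, and the interferon list of R3 in the stable state, at 0.58, lay farthest from the rest.

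Setting selected against stable cells compares the same 5 sublines with and without the inhibitor, at different passages. In selected cells 284 genes were higher and 113 lower, 397 in all. With subline as a block 906 passed (665 higher and 241 lower), 379 of them shared with the first count. MMP1, a collagenase, rose by 2.16 (SE 0.31), the R-spondin receptor LGR5 by 1.96 (SE 0.29), the immediate early gene FOS by 1.94 (SE 0.26) and PRSS12 by 1.72 (SE 0.23), followed by SDCBP at 1.36, MAMDC2 at 1.35, GPNMB at 1.33 and the mechanosensitive channel PIEZO2 at 1.28. The small heat shock protein CRYAB fell at -1.59 (SE 0.22), the mitochondrial carriers UCP2 and SLC25A11 at -1.21 and -1.10, CFAP44 at -1.17, the integrin ITGB3 at -1.13, EBF3 at -1.09, ORMDL2 at -1.07 and TMEM141 at -1.04. Adjusted p for these 16 genes lay between 0.00900 and 0.0462. Rises and falls here are those of selected relative to stable cells. FOS lay at 10.44 to 11.31 in parental, 10.05 to 10.92 in selected and 8.01 to 9.46 in stable arrays. Every stable array thus lay below every parental one, and no selected array lay above the highest parental one. FOS did not pass for stable against parental, however. CCNE1 differed by 0.39 (SE 0.13, adjusted p = 0.150) and CDK2 by 0.05 (SE 0.11, adjusted p = 0.866), and neither passed.

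The lysosome list was again called higher, with 7 of 27 genes higher and 0 lower (16 and 0 adjusted over the list alone), including CTSL at 0.65, SMPD1 at 0.64, CTSD at 0.44 and MCOLN1 at 0.36 (adjusted p = 2.09e-09, and adjusted p = 0.436 with an estimated correlation). The background mean was lower in the selected array of all 5 pairs. Of 35 oxidative phosphorylation genes 2 were higher, NDUFS3 at 0.46 and UQCRC2 at 0.36 (4 with the block, and 13 and 0 lower adjusted over the list alone, adjusted p = 2.32e-07, and adjusted p = 0.436 with an estimated correlation). Ribosomal protein genes were lower in 3 of 36, RPS24 at -0.73, RPL13 at -0.59 and RPL7A at -0.42, and higher in 0 (1 with the block, and 5 lower and 1 higher adjusted over the list alone, adjusted p = 2.6e-05, and adjusted p = 0.436 with an estimated correlation). Of the p53 targets CDKN1A rose by 0.64, DDB2 by 0.54, ZMAT3 by 0.48 and SESN1 by 0.44. These were 4 of 23 (7 with the block, and 8 higher and 1 lower adjusted over the list alone, adjusted p = 0.0237, and adjusted p = 0.995 with an estimated correlation). Higher as lists, each with adjusted p = 0.995 with an estimated correlation, were the centrosome (adjusted p = 0.0237), epithelial (adjusted p = 0.0298) and CDK2 and cyclin E genes (adjusted p = 0.0448), with 0, 0 and 1 genes higher alone and 0, 4 and 2 with the block. Among single genes EGR1 was higher by 0.97, MMP10 by 1.20, AKR1C3 by 0.50, CCND3 by 0.36, MCM2 by 0.33, E2F1 by 0.33 and FEN1 by 0.25. EGR1 lay at 12.14 to 12.82 in parental, 11.75 to 12.17 in selected and 10.30 to 11.83 in stable arrays. AURKB and GINS4 fell at -0.50 and -0.86. CCNE2, at 0.76, did not pass (adjusted p = 0.0979). With subline as a block CCNE2 passed (adjusted p = 0.0378) and FEN1 did not (adjusted p = 0.0633).

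This comparison rested on few arrays, and none of the 38 called genes named for it kept its call in all alternatives. Leaving out both arrays of R7 left 0 genes (159 with the block). The block together with the olfactory receptor mean left 0 (MMP1 at 1.24, MMP10 at 0.77, E2F1 at 0.21, CCND3 at 0.20, MCM2 at 0.19 and MCOLN1 at 0.16). The olfactory receptor mean as a covariate without the block gave 529 genes, 292 higher and 237 lower. Of these, 342 were among the 397 called without it, in the same direction. Single arrays left out gave 86 to 962, and centring each array on its median gave 177 higher and 115 lower. Of 24 alternatives FEN1 lost its call in 18, MCM2 in 16, EGR1, E2F1 and CCND3 in 15 and GPNMB and MCOLN1 in 14, the CDK2 and cyclin E, centrosome and epithelial lists lost theirs in 11 of 18 and the p53 list in 10, and with the mean of all rows of a gene PIEZO2 fell to 0.54 (adjusted p = 0.0489) and RPL13 lost its call at -0.13 (adjusted p = 0.466).

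One gene, AQP5, was called in the same direction in both resistant states, at -0.85 (SE 0.17, adjusted p = 0.0136) in selected and -1.01 in stable cells. Both comparisons use the same 4 parental arrays. Of the 1273 genes called in selected cells, 1067 (83.8%) differed in the same direction in stable cells. In simulations of unchanged groups against the same controls, as many genes of smallest p agreed in direction in 90.5% on average (89.2% to 91.5%), and all genes in 68.8%. Splitting the parental arrays, in each of 6 ways, gave 72.7% to 86.0% (simulated 83.3% to 87.6%), so these shares do not exceed those of unchanged groups. The median difference of the genes called higher was 0.49 in selected and 0.13 in stable cells, and of those called lower -0.46 and -0.16. Across all genes, which are not independent replicates, the differences correlated at r = 0.463 (simulated 0.556) with a covariance of 0.0153 (simulated 0.00921), and with split parental arrays r lay between 0.013 and 0.359 (simulated -0.0295 to 0.0204). Simulated genes vary independently, unlike real ones, so these values leave open how much of the agreement comes from the shared controls.

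Each subline, with its 2 arrays as 1 group, was also set against the parental arrays. In R3 36 genes were called, 22 higher and 14 lower, and in R5 11, of which 4 were higher and 7 lower. In R1, R6 and R7 limma called 0, with 3450, 1354 and 965 genes at an unadjusted p under 0.05. The 2 arrays of a subline differ in growth condition, and this fit counts that difference as spread. With a growth condition term, genes called in at least 1 subline went from 41 to 144. In R3 OSMR, a subunit of the oncostatin M receptor, rose by 2.04 (SE 0.20, adjusted p = 0.00423), QPCT by 1.72 and FGFR1OP2 by 1.54. VIT, LIX1 and the WNT antagonist SFRP1 fell at -2.01, -1.99 and -1.86. In R5 OSMR rose by 1.61 (SE 0.20, adjusted p = 0.0149), NPNT by 1.48 and LETM2 by 1.18. VIT, LTBP1 and the stress response regulator ATF4 fell at -2.06, -1.44 and -1.33. The 41 genes called in at least 1 subline became 19, 14 and 13 without parental replicates 1, 2 and 4, 240 without the selected array of R3 and 21 without its stable array, 21 without either array of R5, 25 without either of R6 and 185 without either of R7. Each of the 6 genes named in R3 and the 6 in R5 lost its call in some of 23 alternatives, NPNT in 8 and LIX1 and SFRP1 in 7. R3 and R5 shared 6 called genes. No gene was called in all 5 sublines. At an unadjusted p under 0.05, 77 genes differed in the same direction in all 5, 35 higher and 42 lower, against a mean of 8.8 and at most 14 in simulations with unchanged groups and shared controls. Simulated genes vary independently, unlike real ones, so the simulated spread of this count may be too narrow. These simulations cannot say whether 77 exceeds chance.

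Between the sublines themselves 22 genes differed, and 2914 had an unadjusted p under 0.05. OSMR spanned 2.54 (adjusted p = 0.0198), from 6.82 in R1 to 9.37 in R3. LGALS13 spanned 1.87, SLC9B1 1.66, CACNA2D1 1.36, GDPD4 1.33, TAAR3P 1.29, ATF4 1.21 and PLCB1 1.18. Each of these 8 genes lost its call in some alternative, and ATF4, GDPD4 and PLCB1 (13 of 20), SLC9B1 and TAAR3P (12 of 19) and CACNA2D1 (10 of 19) in most, with SLC9B1 at 0.98 (adjusted p = 0.0562) under the mean of all rows. Some of these genes also spread widely among the 4 parental arrays. SLC9B1 lay there at 5.86 to 7.59, GDPD4 at 7.33 to 8.55, LGALS13 at 7.63 to 8.55 and TAAR3P at 6.17 to 6.98. CACNA2D1, at 6.23 to 6.49, and PLCB1, at 8.87 to 8.95, spread less there. Of the 22, 3 were olfactory receptor genes, 1 an olfactory receptor pseudogene and 3 small nucleolar RNA genes. With the olfactory receptor mean as a covariate (GDPD4 at 0.86 and TAAR3P at 0.81), or with quantile normalization, 0 genes were called. Without both arrays of R7 305 were called, without any 1 array of R5 or R7 0, without any 1 of R1 or R6 3 to 11, and without the selected array of R3 410. CCNE1 and CDK2 did not differ between sublines by more than the spread within them (adjusted p = 0.426 and 0.589).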

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

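Tests of single outlying arrays were run on every named gene and list mean in the groups of 4 and 5 arrays, 408 groups of values, and 20 were marked as having 1 array far from the rest. Chance marks about 1 in 20 such groups, so this number is what chance gives.

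In stable arrays R1 stood apart for FOS at 9.46, where the other 4 lay between 8.02 and 8.20, and for C19orf12 at 9.17, SMPD1 at 8.14 and TAP1 at 8.43. R7 was low for ABCA4 at 7.57 and SDHA at 10.17. R3 was low for SFRP1 at 7.73, where the other 4 lay between 9.49 and 10.04, and its mean of the NF-kB list was high at 0.079 relative to parental. In selected arrays R3 was high for FGFR1OP2 at 8.75 and low for ORMDL2 at 9.35, and R6 was low for CCND3 at 10.24 and high for FOSB at 9.16. Among parental arrays replicate 3 was low for DDB2 at 8.64, ICAM1 at 8.44, the MAPK list at -0.18 and the BCL2 family list at -0.061. Parental replicate 1 was high for HERC5 at 6.88 and LETM2 at 7.68, and parental replicate 2 was low for MAL at 10.29 and high for URI1 at 12.74.

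The sublines differed from each other in 22 genes by the F test, as described with the comparison between sublines. Of the 11771 table rows with no gene name here, 3 were called between selected and parental arrays, 1 higher and 2 lower, adjusted over these rows.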

How the results depend on the processing

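The olfactory receptor covariate and the fits without R7 were chosen after seeing the data. The causes of the shifts below were not tested, except that a minimum difference or fewer arrays narrows a test by construction. Array number and signal over background limit every count, since dim genes sit near background and the steps before deposit are unknown.

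Selected against parental (1273 genes) moved to 44 with a log2 difference of at least 1 and to 2318 with the covariate, and to between 517 and 1343 with 1 array left out. All other settings stayed within 1.5 times of the total, but the share of higher genes did not hold (487 higher and 375 lower without parental replicate 3).

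Stable against parental (1 gene) gave 5 with trended and robust variance, 286 with array weights, 2 with median centring, 4 with the filter on dim genes, 8 with 1 fit of all 14 arrays, 7 with that fit and subline as a random block and 75 with the covariate, and between 1 and 26 with 1 array left out. Selected and stable shared 0 genes (1 otherwise) with a difference of at least 1, 3 with trended variance, 120 with array weights, 2 with the dim filter, 5 and 4 with all 14 arrays without and with the random block and 51 with the covariate, and between 1 and 8 with 1 array left out.

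Selected against stable (397 genes) gave 29 with a difference of at least 1, 1480 with array weights and 614 with quantile normalization. It gave 197 with all rows one by one, and 680 and 1367 with all 14 arrays without and with the random block. It gave 906 with the subline as a replicate block, 529 with the covariate alone (292 higher and 237 lower), and 0 with that block and the covariate. Without subline R7 it gave 0, and 159 with the replicate block. With 1 array left out it gave 86 to 962, and R3 selected, R7 selected, R5 stable and R7 stable each took it to 104 or fewer (86, 97, 104 and 102).

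Genes called in at least 1 subline (41) numbered 67 with trended variance, 1418 with array weights, 62 with quantile normalization, 27 with median centring, 16 with all rows one by one, 144 with a growth condition term and 115 with the covariate, and between 13 and 240 with 1 array left out. No setting called a gene in all 5 sublines. Genes that differ between sublines (22) numbered 584 with trended variance, 1389 with array weights, 8 with median centring, 305 without R7, and 0 with each of quantile normalization, all rows one by one, no growth term and the covariate, and between 0 and 410 with 1 array left out.

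No named gene or list reversed a called direction under any setting. Over all fits, named genes lost a call in 573 and gained one in 51, and lists in 86 and 51. Of named called genes, 28 of 59 for selected against parental, AQP5 for stable against parental, and 0 of 38 for selected against stable kept their call in all alternatives that set no minimum difference, and 0 of 6 in R3, 0 of 6 in R5 and 0 of 8 between sublines. Of the 28, 14 had a log2 difference of at least 1, a setting not run gene by gene. No called list kept its call in all. With the replicate block 37 of 38 named calls of selected against stable were kept, CCNE2 passed, and no list changed its call by camera.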

Other observations

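The runs of neighbouring genes, their length of 50 genes and the shift of 0.1 used to pick them were chosen after the data were seen, as were the tests below, except those on other splits of the arrays and the intercept over the 5 pairs of the lysosome list, which were written down before their results were seen.

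Genes at or above the 40th percentile of mean signal were put in the order of the GRCh38.p14 gene table. They were cut into 208 runs of 50 neighbouring genes, 10400 genes in all. Run means were taken relative to the parental mean, and each array was centred on the median of its runs. In 31 runs the sublines differed from parental cells, 12 lower and 19 higher. In 4 of them the run mean was shifted by more than 0.1 in the same direction in all 10 resistant arrays. The runs from MPST to XPNPEP3 and from RBX1 to TTC38, which follow each other, were lower by -0.28 (SE 0.03) and -0.20 (SE 0.03), and the runs from PIGM to METTL13 and from NEMF to PCNX4 were higher by 0.19 (SE 0.02) and 0.20 (SE 0.03). Of the 36 genes called in R3, 9 lay in 1 run, from MGST1 to ZCRB1, and all 9 were higher (INTS13, FGFR1OP2, TM7SF3, MED21, STK38L, BMAL2, MRPS35, KLHL42 and ERGIC2). That run's mean was 0.28 above parental in the selected and 0.64 in the stable array of R3. It was also 0.13, 0.17 and 0.10 above parental in R1, R5 and R7, and -0.01 in R6. By an F test between sublines this run did not pass (adjusted p = 0.161), and 0 of the 208 runs did. The 9 genes were named after their values were seen.

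The run from MPST to XPNPEP3 may mark a genomic segment that changed in copy number before or during the derivation of all 5 sublines. When the run was picked on every other gene, all 10 resistant arrays lay below the lowest parental array over the 25 genes not used to pick it. Of its 50 genes 96% were lower, which argues against a few genes, although the run was picked on these same genes. After removing the slope on the background measure 10 of 10 arrays still lay below the parental ones. The run was picked for being lower in all 10, and the slope was not re-estimated without single parental arrays. This count therefore does not settle whether array background contributed. No DNA was measured here, and regulation shared by neighbours or a parental culture that differed from the one the sublines came from stay open.

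The lysosome list averaged higher in selected arrays. With the olfactory receptor mean as a covariate the difference from parental was 0.30, against 0.32 without it. That mean differed by only -0.079 between selected and parental arrays, so the covariate had little to remove. The result argues against array background there only as far as this measure tracks it. White blood cells are argued against by the leukocyte list, whose mean differed by -0.013, with CD68 at 0.18 and LCP1 at 0.11. Presence of the inhibitor is consistent with the list being higher in the selected array of 5 of 5 sublines, but passage differed too, and for this comparison background stays open, since the intercept over the 5 pairs was 0.19 (SE 0.12) against a plain difference of 0.31.

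The selected and stable arrays of R7 were unlike each other. Their run profiles correlated across runs, which are not independent replicates, at 0.136, and the other 4 pairs at 0.549 to 0.902, while the selected array of R7 correlated at 0.874 with the stable array of R1. R7 was not alone in this, since the selected arrays of R3 and R5 also matched each other better (0.783) than their own partners (0.549 and 0.700). Removing the background slope estimated in the 4 parental arrays raised the R7 pair to 0.443, against a lowest other pair of 0.497, but this moved between 0.167 and 0.735 when 1 parental array was left out of the slope, so array background cannot be told apart from a real difference. Profiles centred on the mean of the 10 arrays gave -0.832 for the R7 pair, against 0.172 to 0.789 for the other 4 pairs. With the background slope removed as well they gave -0.666, against 0.120 to 0.662. Centring lowered the correlation of every pair, but the R7 pair stayed the lowest. Centred profiles were not used to decide, and their slope was not re-estimated without single parental arrays. With the slope removed, the selected array of R7 matched that of R6 best (0.838), not R1. A wrong label on an R7 array is not singled out by these matches and stays open, and leaving out R7 took the calls between selected and stable cells to 0, or to 159 with the subline block.

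For selected against parental 1 of 100 splits of the arrays, the real one, gave 1273 genes and the highest other gave 396. Such splits treat the arrays as separate cultures, which the labels do not state for the parental ones. A chance difference between cultures is therefore not excluded. Chance cannot be excluded for stable against parental either, where 7 of 100 splits gave at least 1 gene. For selected against stable 3 of 100 splits gave at least 397, 2 of them more than the real one. These splits ignore the pairing by subline. The highest other splits gave 3084 genes for stable against parental and 4776 for selected against stable, which points to a structure of the samples. Their gaps in the olfactory receptor mean, 0.318 and 0.365, were reached by 3 and 1 of the 126 splits, so these splits follow array background more than the real ones do. Among the 16 splits that part all 5 pairs, 1 gave as many genes as the real 906 and the highest other gave 0, but 16 splits are too few for a share under 0.05. For the runs, 1 of 100 splits gave 31 and the highest other gave 23.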
